A study of Mus musculus with 6 samples.

How the data were processed

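The series holds 6 RNA-seq libraries, 3 labelled Control and 3 labelled Eed KO. Per the labels' protocols, back skin was taken at 5 months and epidermal cells were sorted as EpCAM-positive, Sca1-positive and high for α6-integrin, a gate for basal cells of the interfollicular epidermis. Libraries were made from 50 ng of total RNA with an mRNA kit and read as 150-nucleotide pairs, per the labels' protocols. In mice given hydroxytamoxifen, 100 µl of a 20 mg/ml solution was put on shaved back skin daily for 4 days from postnatal day 50. The labels give the control mice as wild type with no treatment and the Eed KO mice as null for Eed and treated, so the drug and the genotype cannot be separated if these entries hold. The treatment protocol has the same text for all 6 samples, and whether controls also got the drug cannot be read from it. No label says that the 3 libraries of a group came from separate mice, so p-values of single genes measure the spread between these samples. Fisher's exact tests below take genes as independent units and do not measure that spread.

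The authors deposited 1 table with 2 columns per library. Its first kind of column holds estimated counts per gene, deposited without normalization: column totals differ between libraries and 5.10% to 6.20% of all values, zeros included, are not whole numbers. Its second kind holds TPM (transcripts per 1000000), deposited per library and scaled by the authors, and each TPM column sums to 1000000 within rounding. STAR 2.7.9a, RSEM 1.3.3, DESeq2 1.38.3 and the genome build mm39 are named, with no role or order, per the submitters' processing notes. The gene annotation and whether counting used strand are not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore be shared between them. RSEM divides reads that match several places, and the division can move between gene copies. The reference annotation at hand (GENCODE M21, build GRCm38) differs from the authors' build, so it served only for gene types and for which genes neighbour each other, and no coordinates are given.

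The table held 55357 genes, of which 21700 had a count in any library. It gave no name for 1362 gene identifiers, and 56 of these were named from the reference table, in which 52081 of the identifiers were found. Genes with no name in the table held 0.00318% to 0.00495% of a library's counts. Estimated counts were rounded to whole numbers for the tests. Totals per library were 13207600, 12207600 and 12562800 counts in controls and 14713200, 10901100 and 12691900 in Eed KO, each rounded to the nearest 100. A count of 3 in a library, the limit that a count of 0 allows, equals 0.239 CPM on average in controls and 0.238 CPM in Eed KO. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

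Counts per 1000000 (CPM) use library sizes scaled by TMM factors, which ranged from 0.979 to 1.02. Means are given with the SD over n = 3 libraries. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 13429 genes. The test was edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest; edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment over these genes and a threshold of 0.05. Every adjusted p of a gene is from this test unless another is named. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of F. For a gene with 0 counts in all 3 libraries of a group, a bound against 3 counts per library replaces the fitted fold, which depends on the prior count. For a gene with 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval.

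Before the data were examined, 31 gene lists were fixed from textbook knowledge of skin and Polycomb biology, none of them chosen on these samples. They covered PRC2 subunits, PRC1 subunits, Hox genes, developmental transcription factors of other lineages, CDK inhibitors, imprinted genes, hyperproliferation and wound genes, proliferation genes, EMT and invasion genes, RAS-MAPK targets, TGF-beta and BMP signalling, the WNT pathway, interferon-stimulated genes, MHC class I antigen presentation and p53 targets. Others held markers of basal, spinous and granular or cornified keratinocytes, hair follicle stem cells, hair shaft and inner root sheath, sebaceous gland, Merkel cells, melanocytes, Langerhans cells and macrophages, T cells, fibroblasts, endothelial and mural cells, and muscle, fat and blood. The last 3 held dissociation stress genes, mitochondrially encoded genes and sex-linked genes. Each list was counted at the threshold over all genes tested and adjusted over the list alone. The 27 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes.

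The genes named were set by a rule written before the data were examined. It takes Eed and the other PRC2 subunits, then annotated genes past the threshold whose groups do not overlap and whose higher mean reaches 1 CPM: the 12 with the largest fold change each way and the 4 with the highest CPM each way. It adds up to 4 members past the threshold from each list, in order of adjusted p, or the 2 with the highest CPM in a list with none. Genes named outside this rule are said to be chosen after their values were seen. Genes coming from near silence were compared by Fisher's exact test, two-sided, with a limit of 0.5 CPM in the lower group.

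Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, and a replicate block. They also took in limma-trend on log2(TPM + 1) with genes of mean TPM 0.1 or more, on log2(TPM + 0.1), and on log2(TPM + 1) with no filter, edgeR's glmTreat against a fold of 1.2, near-silent limits of 0.25 and 1 CPM, camera with an estimated correlation, fry, and each library left out in turn. A fit on protein-coding genes only was chosen after seeing the data. The fits were tested on simulated counts for this comparison with the 13429 genes and known changes. There edgeR called 42.6% of genes changed 1.5-fold, 60.6% of those changed 2-fold and 81.8% of those changed 4-fold, none with the wrong sign. Of its 145 calls 6.21% were false. False calls made up 12.3% of 162 with DESeq2, 3.76% of 133 with limma-voom and 4.93% of 142 with limma-trend. Camera gave p = 2.23e-26 for a simulated list of changed genes and p = 0.634 for one of unchanged genes (n = 29 genes in each). Simulated counts were drawn independently for each gene, so these p-values do not test the preset correlation.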

Results

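RNA-seq was done on basal epidermal cells sorted from the back skin of control mice and of mice with an inducible deletion of Eed in keratin 14-expressing cells (Eed KO). Eed is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27 and keeps target genes silent. There were 3 libraries in each group, with 10901100 to 14713200 counts each, and the comparison asks how the transcriptome of these cells differs after loss of Eed. Spearman correlations of log2 CPM were 0.981 to 0.991 within a group and 0.972 to 0.981 between groups, and the first principal component, with 41.9% of the variance, separated the groups. Counts of each pair of libraries in a group differed by more than sampling noise (chi-square per degree of freedom 5.21 to 32.7). Mitochondrial transcripts made up 1.91% to 2.51% of counts, and Krt5 or the ribosomal gene Rn18s-rs5 was the most abundant gene at 1.61% to 2.77%. All 6 libraries had 2193 to 3417 counts from Y-linked genes and at most 5 from Xist.

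Eed (ENSMUSG00000030619) was at 32.8 ± 2.07 CPM (SD, n = 3) in controls and 20.4 ± 2.71 CPM in Eed KO, and all 3 Eed KO libraries lay below all 3 controls. It fell by 0.68 on the log2 scale (SE 0.15, adjusted p = 0.0149), to 0.622 of the control level. Which exons were deleted is not given in the sources used here, and reads from exons outside the deleted part, or from cells that kept the gene, would still be counted. Of the 13 PRC2 subunits tested, Eed alone passed the threshold, over all genes and when adjusted over the list alone. Epop was at 9.43 ± 4.43 CPM in controls and 15.7 ± 1.46 CPM in Eed KO and missed the threshold (adjusted p = 0.209), though not under every alternative setting. The methyltransferases Ezh2 (58.9 ± 6.91 and 54.8 ± 4.00 CPM) and Ezh1 (69.8 ± 8.45 and 64.5 ± 7.64 CPM) and the subunit Suz12 (59.6 ± 6.54 and 51.5 ± 6.14 CPM) differed by less than the test could call, with adjusted p of 0.671, 0.657 and 0.375. The list's median log2 fold change was −0.11 (camera adjusted p = 0.293). The fall of Eed lost its call without Eed KO replicate 1 (adjusted p = 0.0847), without Eed KO replicate 3 (adjusted p = 0.102), and with limma on log2 TPM values (log2 fold change −0.58 or −0.59, adjusted p = 0.142 to 0.234).

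**Figure D1:**
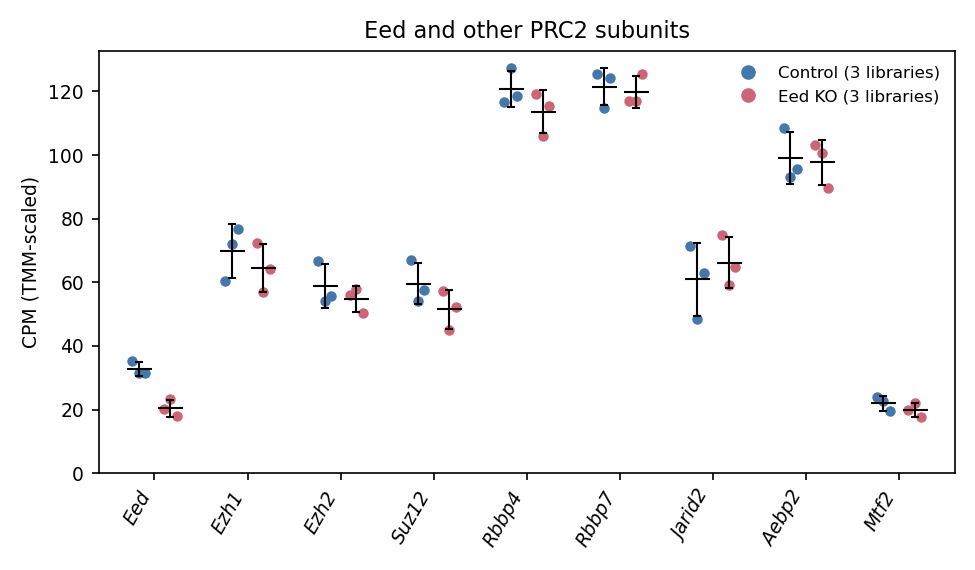
CPM of Eed and 8 other PRC2 subunits, with points for the 3 libraries of each group and black lines for the mean and SD. Eed was at 32.8 CPM in controls and 20.4 CPM in Eed KO without overlap.

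Of 13429 genes tested, 407 were higher and 289 lower in Eed KO. Of these, 218 rose and 40 fell by at least 2-fold. The largest rises by the naming rule, which ranks by the fitted fold, were of genes with 0 counts in every control library. Fitted folds of such genes depend on the prior count. They therefore cannot be ranked against genes with counts in controls, such as Krt2 (83.6-fold). The first were the long noncoding RNA Miat (7.80 ± 2.34 CPM, at least 32.7-fold higher), the hindlimb homeobox gene Pitx1 (7.62 ± 1.18 CPM, at least 31.9-fold) and the zinc finger gene Zic1 (6.98 ± 1.23 CPM, at least 29.2-fold). Next came the AMPA receptor gene Gria3 (5.49 ± 1.18 CPM) and the WNT inhibitor Wif1 (4.88 ± 1.32 CPM, at least 20.4-fold). The adjusted p values of these genes ran from 2.90e-05 for Pitx1 to 0.000278 for Wif1. Igf2bp1, Col14a1, Osr2, Isl1, Sim2 and Cdkn2a were among those that followed, each at least 11.7-fold higher. Among 696 called genes, 694 had groups that did not overlap. Over all tested genes 3531 did (26.3%), where chance gives 10% for 3 against 3. Single libraries moved the counts: 255 genes were higher and 179 lower without Control replicate 3, 124 and 63 without Eed KO replicate 1, and 149 and 66 without Eed KO replicate 3. Counts were larger with limma-voom (583 and 538, 52.0% higher) and with no low-count filter (705 and 553). With limma on log2(TPM + 1), 64 were higher and 22 lower, a share of 74.4% higher against 58.5%. Of 87 called genes that the rule named besides Eed, 25 stayed called under every setting that tested them, among them Pitx1, Wif1, Igf2bp1, Isl1, Cdkn2a, Barx2, Igf2, Krt8, Krt2, Krt77, Krt17, Krt79, Calml3, Sprr2a2, Stfa3, Tnc, Sox9, Dcn, Mcam, Zc3h11a, Slc15a2, Pkib, Gpc3 and Clca3a2. The other 62 lost the call in at least 1 setting, most often on TPM values.

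**Figure D2:**
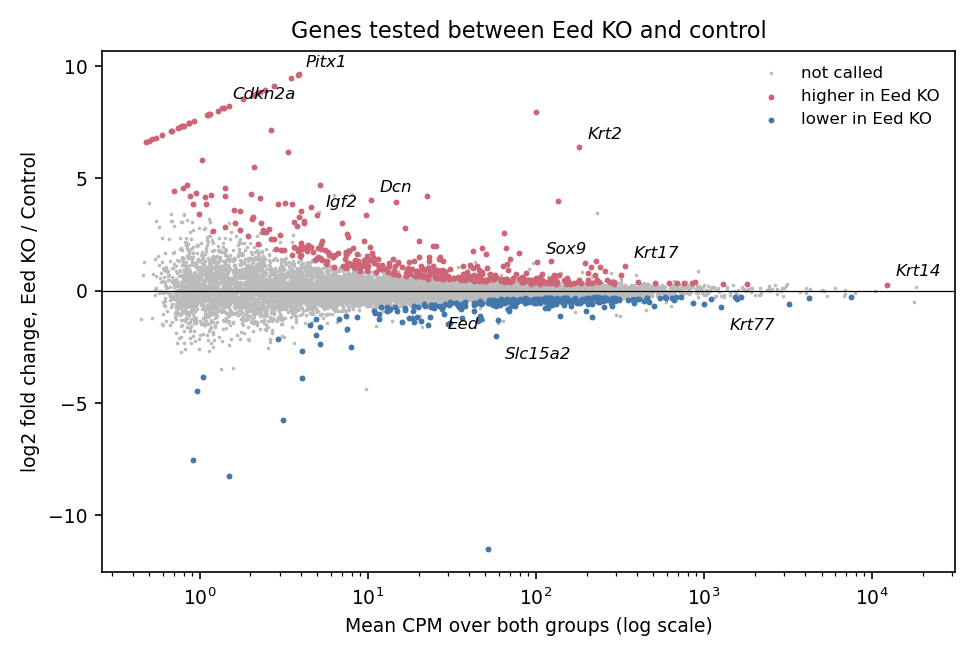
Log2 fold change of Eed KO over control against mean CPM (log scale) for the 13429 genes tested, with 407 genes called higher in red and 289 called lower in blue. The line of red points at the upper left holds genes with 0 counts in all controls, whose plotted fold depends on the prior count.

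Genes that were near silent in controls made up more of the rise than genes near silent in Eed KO made up of the fall. Of 407 genes that rose, 64 (15.7%) had a control mean under 0.5 CPM, and 33 had 0 counts in all 3 controls. Of 289 that fell, 7 (2.42%) had an Eed KO mean under 0.5 CPM, and 2 had 0 counts in all 3 Eed KO libraries. The shares differed by 13.3 points (Fisher's exact test, two-sided, p = 1.28e-09). Without Eed KO replicate 3 the difference was 3.14 points (Fisher's exact test, p = 0.686).

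Developmental transcription factors of other lineages rose together. Of 146 genes fixed in this list 30 were tested, and 18 rose and 1 fell, or 21 and 1 when adjusted over the list alone. Their median log2 fold change was 1.03, also with zero-control genes set at their bounds, and camera gave adjusted p = 1.62e-23, or adjusted p = 0.0177 with an estimated correlation. Barx2, a homeobox gene with expression in control cells too, rose from 46.8 ± 4.79 to 88.8 ± 3.48 CPM (log2 fold change 0.92, SE 0.11, adjusted p = 0.000167). Chosen after its values were seen, Gata4, a heart and endoderm regulator, rose from 0 counts to 2.21 ± 0.807 CPM, at least 9.26-fold higher (adjusted p = 0.00518). Gata4 lost its call without Eed KO replicate 1 (adjusted p = 0.0565). The 1 gene that fell was Tfap2b, from 131 ± 8.39 to 97.2 ± 3.15 CPM (adjusted p = 0.0113, and up to 0.0882 without Eed KO replicate 1 or 3), also named after its values were seen.

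Hox genes did not move as a list. Of 25 tested, 4 rose and 2 fell, or 6 and 3 adjusted over the list alone. The median log2 fold change was −0.18, the mean was 0.64 and camera's direction was down (adjusted p = 0.743). Hoxd10 went from 0 counts to 2.56 ± 0.327 CPM, at least 10.7-fold higher (adjusted p = 0.00266), and Hoxd13 to 1.72 ± 0.716 CPM, at least 7.21-fold higher (adjusted p = 0.0101). Hoxa7 fell from 136 ± 7.43 to 95.7 ± 5.53 CPM (adjusted p = 0.00414) and Hoxc6 from 16.9 ± 0.785 to 9.01 ± 2.73 CPM (adjusted p = 0.0395). The call of Hoxd13 was lost without Eed KO replicate 1 or 3 (adjusted p up to 0.0882), that of Hoxa7 without Eed KO replicate 3 (adjusted p = 0.0505), and that of Hoxc6 without any of the 6 libraries (adjusted p = 0.0550 to 0.175).

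The CDK inhibitor genes at the Cdkn2a locus rose. Cdkn2a, which encodes p16 and ARF, had 0 counts in controls and 2.78 ± 0.856 CPM in Eed KO, at least 11.7-fold higher (adjusted p = 0.00241). Cdkn2b rose from 4.87 ± 1.26 to 9.97 ± 0.826 CPM (log2 fold change 1.03, SE 0.27, adjusted p = 0.0400). Of 7 CDK inhibitor genes tested 2 rose and none fell (3 and 0 adjusted over the list alone), with camera adjusted p = 0.0118, and adjusted p = 0.164 with an estimated correlation. Cdkn2b lost its call without Control replicate 2 or 3 or any 1 of the 3 Eed KO libraries (adjusted p up to 0.166). Of 21 PRC1 subunits 1 rose, Cbx6, from 3.21 ± 0.0654 to 9.15 ± 1.03 CPM (adjusted p = 0.00559, and 0.0536 without Eed KO replicate 1), and the list did not differ (1 and 0 adjusted over the list alone, camera adjusted p = 0.857).

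**Figure D3:**
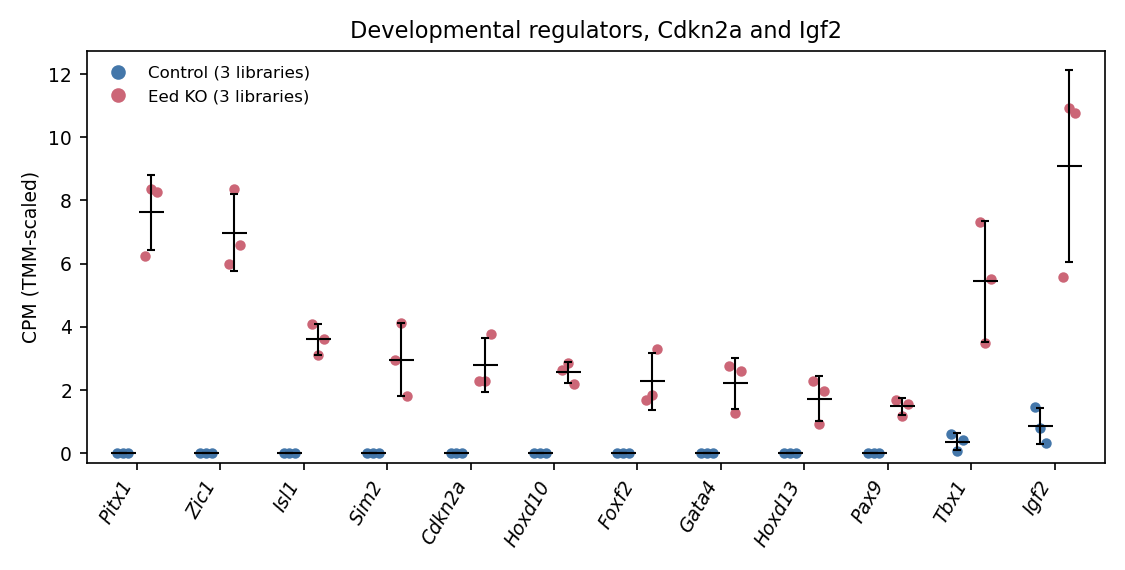
CPM of 10 developmental regulators, Cdkn2a and Igf2, with points for the 3 libraries of each group and black lines for the mean and SD. From Pitx1 to Pax9 the controls hold 0 counts; Tbx1 and Igf2 had counts in controls. Foxf2, Gata4, Pax9 and Tbx1 were chosen after their values were seen.

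Keratin genes changed in both directions. Krt2, a keratin of suprabasal cells, rose from 4.28 ± 0.238 to 358 ± 43.2 CPM (log2 fold change 6.39, SE 0.13, adjusted p = 2.42e-13), an 83.6-fold rise. Krt77, also a suprabasal keratin, fell from 1572 ± 125 to 939 ± 14.6 CPM (log2 fold change −0.74, SE 0.08, adjusted p = 5.13e-05). The calmodulin-like gene Calml3 rose 2.84-fold to 39.7 ± 7.64 CPM (adjusted p = 0.000105). Of 28 spinous keratinocyte genes 5 rose and 3 fell (7 and 4 adjusted over the list alone), with a median log2 fold change of 0.09 and camera adjusted p = 1.53e-05, and adjusted p = 0.278 with an estimated correlation. Of 25 basal keratinocyte genes 1 rose and 1 fell (1 and 3 adjusted over the list alone, median 0.02, mean 0.02, camera direction down, adjusted p = 0.819). Krt14 rose by 0.27 on the log2 scale to 13450 ± 628 CPM (adjusted p = 0.0489), and Postn, the matrix protein periostin, fell from 1027 ± 67.5 to 693 ± 22.6 CPM (adjusted p = 0.000491). Krt14 lost its call without any 1 of 5 libraries (all but Control replicate 3, adjusted p up to 0.255). Of 24 granular and cornified envelope genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.352): the lipid transporter Abca12 fell from 209 ± 28.9 to 141 ± 13 CPM (adjusted p = 0.00677), Casp14 fell (adjusted p = 0.0112) and Serpinb12 rose (adjusted p = 0.0186). The last 2 calls were lost without Eed KO replicate 1 or 3 (adjusted p up to 0.0640 and 0.124), and Serpinb12 also without Control replicate 2 (adjusted p = 0.0513). The granular and cornified list was called higher without Control replicate 1 or Eed KO replicate 2 (lowest adjusted p = 0.0140).

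Hyperproliferation and wound genes were higher in Eed KO, while genes of the cell cycle were not. Of 21 hyperproliferation and wound genes 5 rose and none fell, or 10 and 1 adjusted over the list alone (median log2 fold change 1.19, camera adjusted p = 9.28e-14, and adjusted p = 0.0548 with an estimated correlation). Krt17, a keratin of follicles and injured epidermis, rose from 216 ± 20.4 to 464 ± 19.5 CPM (log2 fold change 1.10, SE 0.08, adjusted p = 4.29e-06). The small proline-rich gene Sprr2a2 rose from 18.5 ± 5.08 to 110 ± 13.9 CPM (log2 fold change 2.57, SE 0.18, adjusted p = 6.86e-06), and the stefin Stfa3 from 41.1 ± 5.48 to 93.6 ± 15.1 CPM (adjusted p = 0.000146). Krt6a, named after its values were seen, was at 38.4 ± 24.5 and 424 ± 153 CPM and missed the threshold (adjusted p = 0.0819). DESeq2 (adjusted p = 2.87e-05), limma-voom (adjusted p = 0.0454) and limma on log2(TPM + 1) (adjusted p = 0.0365) called Krt6a. It was not called by limma on log2(TPM + 0.1), nor by edgeR with any 1 library left out. Of 40 proliferation genes none was called either way, over all genes or adjusted over the list alone (median log2 fold change −0.02, camera adjusted p = 0.788). Mki67 was at 511 ± 34.1 and 487 ± 5.70 CPM (adjusted p = 0.647), and Top2a at 289 ± 33.3 and 242 ± 19 CPM (adjusted p = 0.146).

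**Figure D4:**
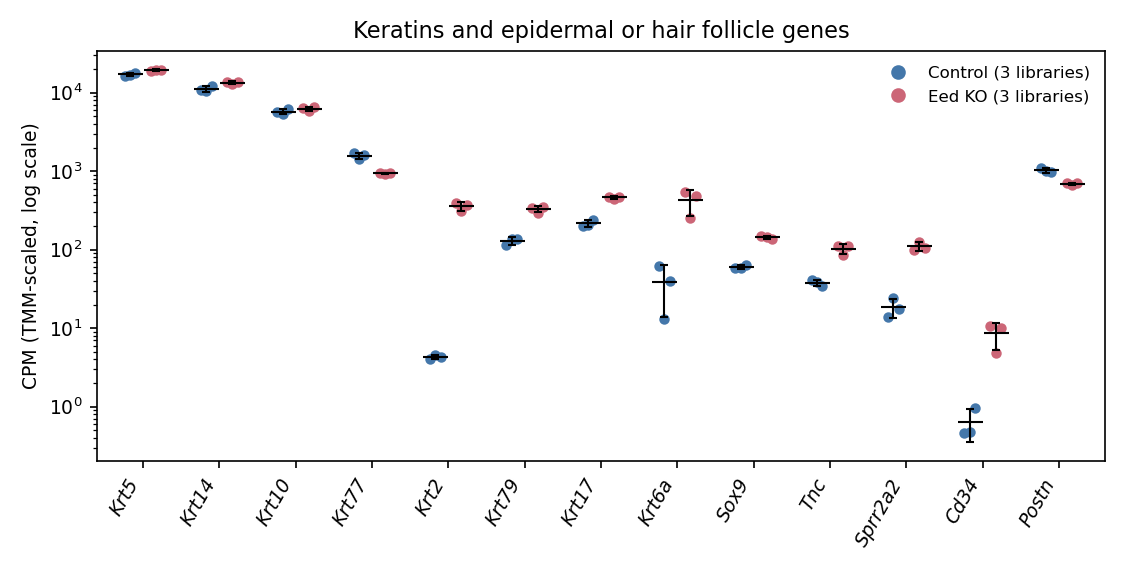
CPM (log scale) of keratins and of epidermal or hair follicle genes, with points for the 3 libraries of each group and black lines for the mean and SD. Krt2 stood at 4.28 CPM in controls and 358 CPM in Eed KO, while Krt77 and Postn were lower in Eed KO. Krt5, Krt10 and Krt6a, chosen after their values were seen, were not called by edgeR.

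Genes of hair follicle stem and progenitor cells rose. Of 22 tested 9 rose and 1 fell (13 and 2 adjusted over the list alone), with a median log2 fold change of 0.75 and camera adjusted p = 9.59e-12, or adjusted p = 0.0354 with an estimated correlation. Sox9, a transcription factor of follicle stem cells, rose from 60.0 ± 2.94 to 144 ± 7.51 CPM (log2 fold change 1.26, SE 0.09, adjusted p = 2.15e-06). Krt79, a keratin of the follicle infundibulum, rose from 130 ± 13.4 to 328 ± 29.1 CPM (adjusted p = 2.29e-06), the matrix gene Tnc from 38.0 ± 3.56 to 102 ± 15.2 CPM (adjusted p = 1.64e-05) and the bulge marker Cd34 from 0.640 ± 0.289 to 8.56 ± 3.22 CPM (adjusted p = 0.000293). The other members that rose, Foxc1, Foxi3, Lhx2, Gli1 and Gli2, were named after their values were seen. Each of them lost its call without Eed KO replicate 1 or 3 (adjusted p up to 0.157). The 1 member that fell was Postn, which the basal list also holds. Of 7 hair shaft and inner root sheath genes 1 rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.204), Selenbp1, from 5.09 ± 1.01 to 11.7 ± 2.12 CPM (adjusted p = 0.0161, up to 0.108 without Eed KO replicate 1 or 3). Of 13 sebaceous gland genes 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.787), the desaturase Scd1, from 352 ± 13.6 to 269 ± 3.42 CPM (adjusted p = 0.00722, up to 0.0654 without Eed KO replicate 1 or 3). Of 3 Merkel cell genes tested, the regulator Isl1 (0 counts to 3.61 ± 0.491 CPM, at least 15.1-fold, adjusted p = 0.000863) and the simple-epithelium keratin Krt8 rose, and adjusted over the list alone 2 rose and 1 fell. Krt8 had 3 counts in controls and 154 in Eed KO, a ratio of 50.3 per count sequenced (95% counting interval 16.9 to 246, adjusted p = 0.00116). The 3 members were too few for camera, and their median log2 fold change was 5.52, or 3.92 with Isl1 at its bound.

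Some fibroblast, endothelial and mural cell genes rose from low levels in the sorted cells. Of 20 fibroblast genes fixed in the list 8 passed the count filter, and of these 6 rose and none fell (7 and 0 adjusted over the list alone). Members with 0 counts in controls, such as Col14a1, passed the filter through Eed KO alone and could only rise. The median log2 fold change of the 8 was 3.16, or 2.88 with zero-control genes at their bounds. Camera gave adjusted p = 3.57e-12, and adjusted p = 0.110 with an estimated correlation. The proteoglycan gene Dcn rose from 1.19 ± 0.752 to 19.6 ± 2.75 CPM (log2 fold change 4.03, SE 0.38, adjusted p = 4.01e-05), and Col14a1 from 0 counts to 4.38 ± 2.86 CPM, at least 18.3-fold (adjusted p = 0.00129). Of 16 endothelial and mural genes fixed 5 passed the count filter, and of these 2 rose (4 and 0 adjusted over the list alone). The median of the 5 was 2.77, with camera adjusted p = 2.61e-06, and adjusted p = 0.0548 with an estimated correlation. Mcam rose from 4.24 ± 1.82 to 29.1 ± 3.83 CPM (adjusted p = 2.90e-05). Flt1 rose from 0.497 ± 0.548 to 4.10 ± 1.84 CPM (adjusted p = 0.0489, up to 0.241 without any 1 of 5 libraries, all but Control replicate 1). Of 26 EMT and invasion genes 2 rose, Cald1 and S100a4 (2 and 0 adjusted over the list alone, camera adjusted p = 0.204, fry adjusted p = 0.0297), and S100a4 lost its call without Control replicate 2 or 3 or Eed KO replicate 1 or 3 (adjusted p up to 0.129). Of 10 Langerhans cell and macrophage genes 1 rose, Mfge8 (1 and 0 adjusted over the list alone, camera adjusted p = 0.358, call of Mfge8 lost without 5 of the 6 libraries, all but Eed KO replicate 2, adjusted p up to 0.184). None of 5 T cell genes (camera adjusted p = 0.887), 4 melanocyte genes or 1 muscle, fat or blood gene was called, and adjusted over the list alone 1 melanocyte gene rose.

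Among growth factor and signalling genes, the imprinted growth factor Igf2 rose from 0.866 ± 0.576 to 9.09 ± 3.04 CPM (log2 fold change 3.36, SE 0.48, adjusted p = 0.000957). The imprinted regulator Plagl1 rose from 20.7 ± 3.73 to 40.5 ± 2.59 CPM (adjusted p = 0.00192). Of 13 imprinted genes 3 rose and none fell (4 and 0 adjusted over the list alone, median 0.42, camera adjusted p = 0.00129, and adjusted p = 0.151 with an estimated correlation). Of 21 TGF-beta and BMP genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 0.0118). That list's call was lost with an estimated correlation (adjusted p = 0.246) and without Control replicate 2 (adjusted p = 0.0790). The latent TGF-beta binding protein gene Ltbp2 rose from 1.70 ± 0.229 to 17.8 ± 7.31 CPM (adjusted p = 6.29e-05) and the BMP antagonist Grem1 from 0.448 ± 0.190 to 6.60 ± 3.28 CPM (adjusted p = 0.00103). Of 28 WNT pathway genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.04, camera adjusted p = 0.306). Wif1 rose from 0 counts to 4.88 ± 1.32 CPM, while the ligand Wnt5a fell from 66.4 ± 19.1 to 27.9 ± 4.72 CPM (log2 fold change −1.26, SE 0.20, adjusted p = 0.00657, and 0.0502 without Eed KO replicate 3). Of 22 RAS-MAPK targets 1 rose and 1 fell, Egr2 and the feedback inhibitor Spred1 (1 and 2 adjusted over the list alone, camera adjusted p = 0.569). The RAS-MAPK list was called without Control replicate 1 (adjusted p = 0.0121). Egr2 lost its call without Control replicate 3 or Eed KO replicate 1 or 3 (adjusted p up to 0.148), and Spred1 without any of the 6 libraries (adjusted p = 0.0564 to 0.141).

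Genes that fell most included Serpina3b, a serine protease inhibitor (13.4 ± 2.44 to 2.34 ± 1.21 CPM, log2 fold change −2.51, SE 0.34, adjusted p = 0.000589), and the peptide transporter Slc15a2 (93.3 ± 19.2 to 22.9 ± 6.91 CPM, log2 fold change −2.03, SE 0.22, adjusted p = 0.00105). Pkib, an inhibitor of protein kinase A, fell from 33.9 ± 2.28 to 11.7 ± 1.91 CPM, the laminin chain Lama1 from 43.8 ± 7.72 to 16.0 ± 6.41 CPM, the prostaglandin D synthase Hpgds from 44.9 ± 1.47 to 16.8 ± 4.19 CPM and the glypican Gpc3 from 23.1 ± 0.879 to 8.79 ± 1.29 CPM. Lama1 and Hpgds lost their calls in all 3 fits of limma on TPM values (adjusted p up to 0.183), while Pkib and Gpc3 kept theirs. Among abundant genes Clca3a2 fell from 3869 ± 154 to 2572 ± 33.3 CPM (adjusted p = 0.000128). One of 2 gene models named Zc3h11a (ENSMUSG00000116275) went from 103 ± 32.6 to 0.0306 ± 0.0530 CPM (adjusted p = 9.95e-06), with 1.1 estimated counts in Eed KO, a ratio of 0.000251 per count sequenced (95% counting interval 6.35e-06 to 0.00140). The other model rose from 69.1 ± 19.6 to 175 ± 11.5 CPM, and the fold change of their sum was 0.03 on the log2 scale (SE 0.10, adjusted p = 0.924).

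MHC class I antigen presentation genes were lower as a list with the preset correlation. Of 19 tested 2 rose and 4 fell (2 and 6 adjusted over the list alone), with a median log2 fold change of −0.28 and camera adjusted p = 0.000949, and adjusted p = 0.463 with an estimated correlation or 0.124 with fry. H2-Q6 fell from 192 ± 27.4 to 87.3 ± 19.7 CPM (adjusted p = 0.00383) and H2-K1 from 1192 ± 89.6 to 799 ± 169 CPM (adjusted p = 0.0378), and the class I regulator Nlrc5 fell from 211 ± 2.51 to 163 ± 2.36 CPM (adjusted p = 0.0101), while H2-D1 rose from 1635 ± 137 to 1988 ± 86.9 CPM (adjusted p = 0.0492). H2 genes are near copies of one another, so their single values are uncertain where reads could be divided between them. In Eed KO replicates 1, 2 and 3, H2-Q6 was at 76.8, 110 and 75.0 CPM, H2-K1 at 684, 993 and 719 CPM and H2-D1 at 2066, 1895 and 2004 CPM. Replicate 2 lay nearest the controls in each of these genes, but not in Nlrc5 (165, 163 and 160 CPM). H2-K1 lost its call without any 1 of 5 libraries (all but Eed KO replicate 2, adjusted p up to 0.124), Nlrc5 without Eed KO replicate 1 or 3 (adjusted p up to 0.0941), and H2-D1 without any of the 6 libraries (adjusted p = 0.0656 to 0.230) and with upper-quartile scaling (adjusted p = 0.0521). Of 28 interferon-stimulated genes 1 fell, Usp18 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0744). Usp18 lost its call without any 1 of 5 libraries (all but Control replicate 2, adjusted p up to 0.199), and the list was called lower without Control replicate 1 or Eed KO replicate 2 and with no low-count filter (lowest adjusted p = 0.0130). Of 25 p53 targets 4 rose (Ddit4, Aen, Gadd45a and Gtse1) and 1 fell (Trp53inp1), or 4 and 1 adjusted over the list alone, with camera adjusted p = 0.293, while fry called the list (adjusted p = 0.0110). Each of the 5 lost its call without at least 1 library (adjusted p up to 0.179), Gadd45a without any of the 6. Gtse1 was named after its values were seen. Of 22 dissociation and stress genes 1 rose and 2 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.688), with Zfp36 falling from 4681 ± 73.3 to 3771 ± 275 CPM (adjusted p = 0.0205, up to 0.155 without Eed KO replicate 1 or 3). None of 12 mitochondrially encoded genes (camera adjusted p = 0.659) or 4 sex-linked genes was called, and adjusted over the list alone 2 sex-linked genes fell.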

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

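The fit on protein-coding genes only was chosen after seeing the data; it gave 413 genes higher and 321 lower. With the listed alternatives no called gene was called the other way, and of 1560 values of the 87 called named genes besides Eed, 1217 kept direction and call, 341 kept direction and lost the call, and 2 reversed. Both were H2-Q5, at 0.0215 with limma on log2(TPM + 1) with or without the filter, against −1.69 (the cause was not tested). DESeq2 gave 515 higher and 371 lower, sharing 688 of the 696 calls, RLE scaling 400 and 294 and upper-quartile scaling 420 and 266. Of the 87 genes, 25 kept their call in every setting that tested them (81 were tested in all).

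Counts of genes higher and lower, from 407 and 289, moved to 705 and 553 with no low-count filter. They were 180 and 54 against a fold of 1.2, a stricter null. On log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter they were 64 and 22, 68 and 26, and 44 and 12; at 2-fold these were 54 and 16, 57 and 17, and 38 and 9, against 218 and 40. The share higher was 72.3% to 78.6% there, against 58.5%. limma-voom gave 583 higher and 538 lower. Genes lower by at least 2-fold numbered 79 with limma-voom and 77 with no low-count filter, against 40. The level of Eed changed by −0.58, −0.59 and −0.58 on the TPM scales without a call. Lists called higher fell from 9 to 2 with an estimated correlation, and lists called lower, 1 in all, were 0 with it and with fry and 2 with no low-count filter. Except where the construction is named, the cause was not tested.

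Leaving out each library gave 124 to 410 genes higher and 63 to 289 lower (by 2-fold, 91 to 218 and 25 to 63), −0.79 to −0.60 for Eed, 1 to 2 lists lower and a near-silent difference of 3.14 to 14.1 points. Counts moved by over 1.5 times without Control replicate 3 (255 and 179), Eed KO replicate 1 (124 and 63) and Eed KO replicate 3 (149 and 66), and 2-fold falls also without Eed KO replicate 2 (63). Fewer samples were then tested. Libraries with the same replicate number did not deviate together (correlations 0.0497, 0.0325 and 0.00636), and with the replicate number as a block 498 genes were higher and 361 lower, and the difference in near-silent genes among the changed genes was 7.75 points (Fisher's exact test, p = 4.85e-06). Depth limits the genes with 0 counts in controls, whose folds are bounds.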

Other observations

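The tests of gene copies, H2 genes, fibroblast genes, hair follicle genes, Hox paralogue groups and symbol families were chosen after the results were seen, and the genes named in the next paragraph were chosen after their values were seen.

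Igfbp2, an IGF-binding protein gene, rose from 2.31 ± 0.456 to 42.8 ± 6.54 CPM (SD, n = 3; edgeR adjusted p = 2.61e-08). The neurotrophin receptor gene Ntrk2 rose from 115 ± 11.5 to 274 ± 2.60 CPM (adjusted p = 1.91e-06), and Megf6 from 27.6 ± 2.37 to 104 ± 14.3 CPM (adjusted p = 9.55e-07). The soluble IL-22 receptor gene Il22ra2 fell from 64.5 ± 7.15 to 25.6 ± 2.32 CPM (adjusted p = 3.06e-05), and the chitinase gene Chit1 from 298 ± 25.8 to 132 ± 12.9 CPM (adjusted p = 6.86e-06). These 5 calls were kept without each library and on TPM values. Among 199 families of gene symbols, with 398 tests adjusted together, keratins were enriched among genes that rose, with 6 of 22 (Krt2, Krt79, Krt17, Krt8, Krt75 and Krt14; Fisher's exact test, adjusted p = 0.00968). Without each library and on TPM values the adjusted p was 4.17e-05 to 0.0938, and the enrichment was lost without Control replicate 1 (5 of 22). Krt75 and Krt14 lost their own calls without Eed KO replicate 1 or 3. The collagen family also passed, but its enrichment was lost without each of the 6 libraries and on TPM values.

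With no low-count filter, 14 of 14 Hox genes of paralogue groups 9 to 13 had a fold change above 0, against 4 of 22 of groups 1 to 8 (Fisher's exact test across genes, p = 1.61e-06). That comparison decides nothing about release of silent Hox genes, since 9 of the 14 had 0 counts in all controls, so that any count in Eed KO puts them above 0, and the groups were formed after the values were seen. Of 20 Merkel cell genes below the count filter, 12 had counts in Eed KO alone, 0 in controls alone, 5 in both groups and 3 in neither. Of the 12, 4 had counts in all 3 Eed KO libraries (named after their values were seen): Pou4f3 (43 counts over 3 libraries), Cck (32), Chga (28) and Sox2 (22). How many of all genes below the filter had counts in Eed KO alone was not counted, so an excess particular to Merkel cell genes is not shown. Genes with any count numbered 16343, 16326 and 17226 in the control libraries and 18169, 16540 and 17345 in the Eed KO libraries.

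Some changes lie in gene copies and in neighbouring genes. Rps3a3 rose from 0.794 to 198 CPM and Rps3a2 from 15.9 to 255 CPM while Rps3a1 fell from 1244 to 961 CPM, but their sum changed by 0.17 on the log2 scale (SE 0.07, adjusted p = 0.191). The sum of both Zc3h11a models changed by 0.025, so a shift of reads between near-identical copies, from variants or from counting, may account for both cases. Of 289 genes that fell, 51 had another within 2 tested genes, against a median of 24 in shuffles (middle 95% 14 to 38), as blocks of strain variants could give, but 80 of 407 that rose did too (median 48), and related neighbours such as Clca3a1 and Clca3a2 remain open. The 51 included Pkib (near Hsf2 and Serinc1), Lama1 (near Epb41l3) and Il22ra2 (near Il20ra). Variants linked to Eed are argued against as the source of these neighbours, since 0 of the 51 lay on its chromosome (7.76% of tested genes), and 0 of 40 genes around Eed were called (5.20% elsewhere), a difference within chance by itself (Fisher's exact p = 0.270). Among 23 H2 genes 52.2% ranged more widely in Eed KO than in controls, against 39.3% of other genes (Fisher's exact p = 0.209), so a mixed H2 haplotype, as in H2-T22 (12.5, 58.1 and 26.4 CPM in the 3 Eed KO libraries), cannot be told apart from a change of the genes themselves with so few genes.

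Fibroblast genes such as Dcn and Col14a1 rose in cells sorted as EpCAM-positive, a gate that removes fibroblasts. Dermal fibroblasts would bring their most abundant transcripts, Col1a1, Col1a2 and Col3a1. In Eed KO these were at 0 to 3.56 CPM, and their joint rise was at most 21.8% of the rise of Dcn in any of the 3 libraries. This argues against dermal fibroblasts as the whole source of the rise of Dcn. Col14a1 rose less than Dcn, to 3.83, 1.84 and 7.47 CPM in Eed KO replicates 1, 2 and 3. The collagens were not compared with Col14a1, so these values do not decide its source. Expression of Dcn and Col14a1 by the epidermal cells themselves may be the source, and other mesenchymal cells were not tested.

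Hair follicle genes rose in a gate meant for interfollicular epidermis. More follicle cells in the sort could raise the markers together, and 16 of 22 tested members lay above 0. Sox9 and Krt79 rose while Postn fell, and Lgr6 (294 and 255 CPM), Lrig1 (274 and 273 CPM), Cxcl14 (500 and 428 CPM) and Krt24 (12.2 and 11.2 CPM) were not called by edgeR, though limma-voom called Lgr6 and Cxcl14 lower (adjusted p = 0.0353 and 0.0211). The limits, set after the values were seen, were all 22 above 0 for the explanation and no more members above 0 than below against it. The count of 16 lies between them, and more follicle cells need not raise members that control cells also express, such as Lgr6 and Cxcl14. More follicle cells and a follicle program in interfollicular cells therefore cannot be told apart.

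The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of them, the real one, gave as many as 696 called genes. The highest of the other splits gave 0. These 10 splits are too few for a share under 0.05.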
